A study of Mus musculus with 2 samples.

How the data were processed

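Single-cell RNA sequencing was done on periodontal ligament, the connective tissue between tooth root and alveolar bone, of male C57BL/6J mice aged 8 weeks. The upper left molar had been pulled forward with a 10-g force for 6 days, and tissue from that side made up the orthodontic tooth movement (OTM) library. Tissue from the unloaded right side made up the control library. Tissue left on the extracted roots and in the sockets was pooled from 5 mice per group, digested with collagenase and then trypsin, and loaded on the 10x Genomics 3' v3.1 chemistry. Each group was therefore represented by 1 library, and no spread between animals could be estimated.

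The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, without normalization, made with Cell Ranger 7.0.1 per the file headers. The submitters' processing notes named the mouse builds mm10 and GRCm38 and the tool Seurat; the Seurat version and any cell filter were not given in the sources used here. All values were whole numbers, and the lowest totals per barcode were 502 UMIs in the control library and 507 in the OTM library. The count matrices held 369 and 1539 barcodes, far fewer than the cell recovery targeted per sample in the labels. Both matrices listed 32285 genes, of which 32158 identifiers were found in GENCODE M21 (GRCm38). The 370 repeated symbols were kept apart by identifier.

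Barcodes with at least 200 detected genes and at most 20% mitochondrial counts were kept. This removed 21 control barcodes (5.69%; 14 had too few genes and 13 too many mitochondrial counts) and 127 OTM barcodes (8.25%; 62 and 106). The 348 control and 1412 OTM cells that remained held 5593726 and 35518568 UMIs. Scrublet, run on each library, called 2 control and 8 OTM cells as doublets, and these were kept in the main values.

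Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 and seed 0, on both libraries together without batch integration. Clusters that scored highest for macrophages or monocytes, osteoclasts or dendritic cells were pooled and clustered again, as were those that scored highest for T or NK cells or mast cells (resolution 0.8, 1500 variable genes, 10 components, 10 neighbours). These clusters carry the letter m or t. A cluster was named from 23 marker lists. The class with the highest score named a cluster, or the next one if it had at least 3 markers among the 10 leading genes. A name needed at least 3 detected markers and a score of at least 0.5. A cluster stayed unnamed when its 10 leading genes held more markers of another class. Classes are called neutrophil-like and so on, because the names rest on transcripts alone. Stromal cells are the fibroblast-like, osteoblast lineage-like and mural-like cells together.

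Counts were summed per library and class, and a level is given in CPM, counts-per-million of the class total. Each sum has an exact 95% Poisson interval, each share an exact Clopper-Pearson interval, each difference of shares an approximate interval that joins those bounds by Newcombe's square-and-add method, and each ratio of OTM over control the exact interval of a conditional binomial. These intervals cover counting error only: they say nothing about variation between mice, and no p-value was computed. Those of sums and ratios also leave out variation between the cells of a class. A ratio against 0 UMIs is given as at least the ratio to a floor of 3 UMIs over the class sum. With 1 to 3 UMIs in a library, the ratio of the counts is given with its interval. List medians use sums under 3 UMIs set to 3, which pulls members with few UMIs toward the library with fewer UMIs.

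The genes named in the text followed a rule written before the data were examined. In neutrophil-like, macrophage or monocyte-like and fibroblast-like cells it took the 10 genes with the highest and the 10 with the lowest log2 ratio. Eligible genes had at least 20 UMIs in the higher library, were detected in at least 10% of the class cells there, and reached at least 10% of the highest CPM of any class with at least 20 cells in that library. Mitochondrial, ribosomal protein, haemoglobin, Gm, Rik, Xist and Y-linked genes and markers of other classes were left out. For the whole library the rule took 5 and 5, and from each gene list 2 to 4 members, the most abundant and those over 2-fold. The same rule with 5 and 5 was also applied to osteoblast lineage-like cells and to an unnamed cluster, which were chosen after the class sizes were seen. The list members named, among those that met this rule, were picked after their values were seen, and Cxcr2 in neutrophil-like cells and Scx in fibroblast-like cells, which lay outside it, were chosen after their values were seen. Other genes outside the rule were likewise chosen after their values were seen. The ligand and receptor pairs were fixed before the data were examined.

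The 27 gene lists were fixed at the same time. They covered neutrophil states (primary granule, secondary granule, late maturation, activation, NADPH oxidase and NETs, survival), signals (recruiting chemokines, osteoclastogenic signals), myeloid functions (osteoclast differentiation, resident macrophage, inflammatory monocyte, MHC class II, phagocytosis and lysosome), tissue programs (fibrillar and ligament matrix, matrix remodelling, YAP and mechanoresponse, tendon and ligament identity, osteoblast and cementoblast, endothelial activation) and general responses (Wnt, TGF-beta and BMP, hypoxia and glycolysis, NF-kB, interferon, cell cycle, dissociation and immediate early, ER stress). For each list and class the median log2 ratio was taken over members with at least 10 UMIs in both sums together. Its percentile among 10000 random lists of the same size, matched on CPM in 10 bins, describes the list against the other genes of these 2 libraries and is not a test. Over all genes the median log2 ratio was -0.20 in fibroblast-like cells, 0.20 in neutrophil-like cells and -0.10 in the whole library, and it lay within 0.1 of 0 in the other compared classes.

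The interval and list procedures were tested on simulated data, drawn as Poisson counts from the mean profile of each class with changes of known size. The ratio intervals held the true value for 96.2%, 96.8% and 96.7% of genes in the neutrophil-like, macrophage or monocyte-like and fibroblast-like settings. Counts were drawn under the model that the intervals assume, so this coverage says nothing about variation between cells. True log2 changes of 2 came back with medians of 2.02, 2.03 and 1.87, and those of -2 with -1.99, -2.00 and -2.21. The interval lay on the right side of 0 for 72.0% to 100% of genes with changes of 2 or -2, but for only 43.2% to 70.2% of those with changes of 1 or -1. A list of 12 genes with a change of 1 reached percentile 100 in each setting, and 40 lists of 12 unchanged genes had median percentiles of 47.6, 64.05 and 48.3.

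Alternatives written before the data were examined were no barcode filter, a stricter filter (500 genes, 10% mitochondrial counts), doublets removed, resolutions 0.5 and 2.0, a class for each cell from its own marker scores, cells thinned to 1500 UMIs, each library clustered alone, totals without other markers, centred ratios, a mean over cells, gene minimums of 50 UMIs and none, and control classes weighted by OTM shares. Added after seeing the data were shares without cluster 1, with cluster m2 and with cluster 0, the class cluster with most control cells alone, cluster 11 alone, and list medians for members with at least 3 UMIs expected in each library at equal CPM. Levels of ligands and receptors were planned for classes of at least 20 cells; smaller classes were added after they were seen. The work used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.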

Results

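The data were UMI counts per gene and cell from 2 libraries of mouse periodontal ligament, 1 from the loaded side after 6 days of a 10-g force and 1 from the unloaded side, each pooled from 5 mice. There were no replicates, so a difference below is a difference between these 2 libraries. The control library held 369 barcodes with 5723299 UMIs and a median of 14107 UMIs per barcode (range 502 to 202268). The OTM library held 1539 barcodes with 36010801 UMIs and a median of 18128 (range 507 to 222392). After filtering, 348 control cells with a median of 14877 UMIs and 1412 OTM cells with a median of 19583 UMIs remained. The smaller control library limited most comparisons.

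The composition of the tissue was compared because the series title names neutrophils as organisers of osteoclast formation during tooth movement. The share of neutrophil-like cells was 9.48% in the control library (33 of 348 cells, 6.62% to 13.1%) and 10.5% in the OTM library (148 of 1412, 8.93% to 12.2%). The difference of 1.00 percentage points had an interval of -2.90 to 4.34, so no difference in this share was detectable at this depth. Endothelial-like cells made up 4.02% of control cells (2.22% to 6.66%) and 14.4% of OTM cells (12.7% to 16.4%). Osteoclast-like cells, the multinucleated cells that resorb bone, were seen as 16 of 1412 OTM cells (1.13%, 0.649% to 1.83%) and as 0 of 348 control cells, which allows a share of up to 0.862% at a limit of 3 cells, or 1.05% as the upper bound of the exact interval.

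Fibroblast-like cells made up 8.91% of control cells (6.13% to 12.4%) and 29.5% of OTM cells (27.2% to 32.0%), and stromal cells together 19.8% and 41.4%. This difference depended on how cells were classed. When cells were thinned to 1500 UMIs, both shares were lower in the OTM library than in the control library. The stromal share was then 54.8% in the control library and 41.5% in the OTM library. When each library was clustered alone, the stromal share was 46.0% and 47.1%. Cluster 0, a stromal cluster with Pcp4 and Wif1 among its leading genes, was 26.1% of control cells and 8.14% of OTM cells. It scored highest for fibroblasts (1.024, against 0.814 for dental pulp), with 11 fibroblast markers detected. It stayed unnamed because its 10 leading genes held a single dental pulp marker, Sfrp2, and no fibroblast marker. Counted as stromal, it brought the shares to 46.0% and 49.5%.

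Macrophage or monocyte-like cells made up 6.61% of control cells (4.24% to 9.75%) and 4.75% of OTM cells (3.70% to 5.99%). The difference in the macrophage monocyte share had an interval of -5.18 to 0.82 percentage points, which included 0. With doublets removed before clustering the shares were 8.38% and 2.49%. Without a filter, with the stricter filter, with each cell's own scores, with thinned cells, with each library clustered alone and with cluster m2, the difference lay between -5.02 and -3.87 points with intervals below 0. Osteoblast lineage-like cells made up 9.20% of control and 8.71% of OTM cells, mural-like cells 1.72% and 3.12%, and epithelial-like cells 3.74% and 6.59%. Unnamed clusters held 46.0% of control cells and 12.8% of OTM cells. Besides cluster 0, these were cluster 1 (14.4% and 0.850%, with a median of 781 UMIs), cluster m2 (3.45% and 1.27%), cluster 14 (2.01% and 2.34%) and 3 OTM cells of cluster t2.

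**Figure D1:**
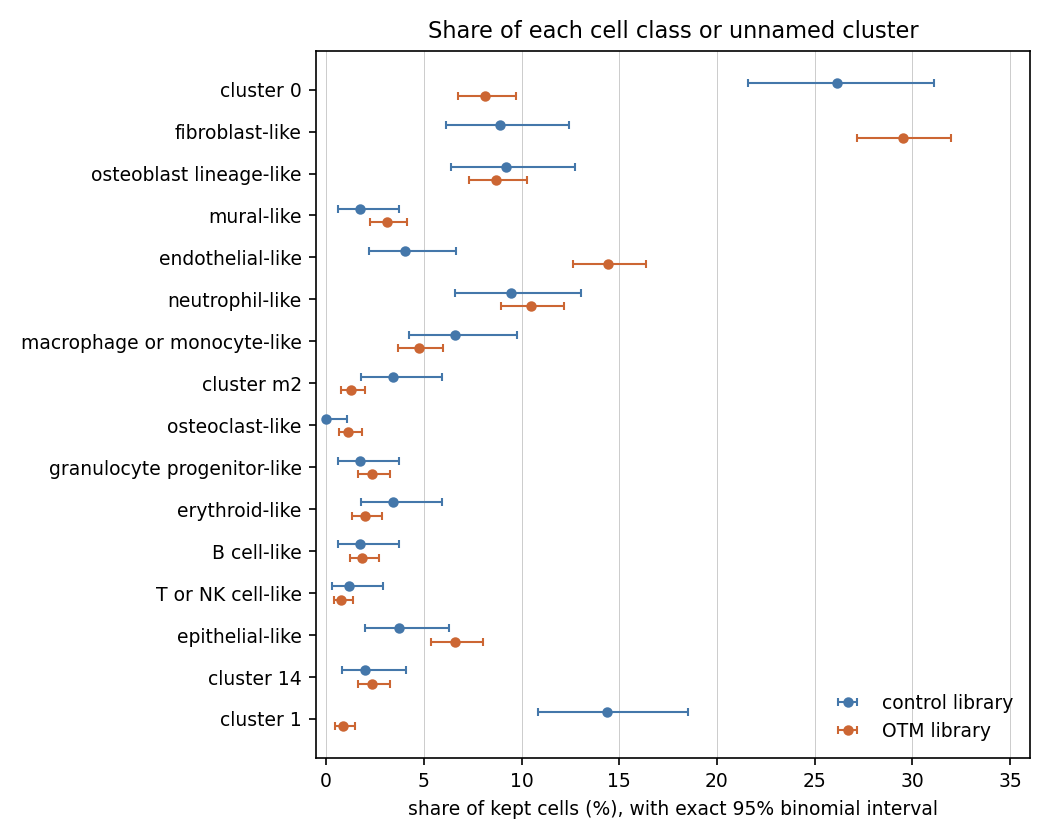
Share of kept cells per class in the control and OTM libraries, in percent, with exact 95% Clopper-Pearson intervals. The neutrophil-like share was 9.48% and 10.5%, and the fibroblast-like share 8.91% and 29.5%.

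Neutrophil-like cells were compared to ask which of their signals differed with loading. The median neutrophil-like cell held 11322 UMIs in the control library and 5412.5 in the OTM library. Genes of neutrophil activation were higher in the OTM library. The ratios here and in the next paragraphs are of the whole class, and values of several of them within its clusters are given below. Il1b, an inflammatory cytokine that promotes bone resorption, was at 1752 CPM in the control library and 5813 CPM in the OTM library, a log2 ratio of 1.73 (1.62 to 1.85). Il1a, the related alarmin, had a log2 ratio of 3.03 (2.31 to 3.85), and Tnf a log2 ratio of 1.69 (1.32 to 2.07). Csf1, a growth factor of macrophages and osteoclast precursors, was at 28.7 and 158 CPM, a log2 ratio of 2.47 (1.59 to 3.49). The gene Il1b (ENSMUSG00000027398) lies on chromosome 2 at 129364570 to 129371139 on the minus strand of GRCm38.

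Of the 22 activation genes, 21 were measured and 17 were at least 2-fold higher, with a median log2 ratio of 1.57 (percentile 100 among random lists). The recruiting chemokines had a median of 1.59 over 14 measured genes, 9 of them at least 2-fold higher. Cxcl2, a neutrophil attractant, was at 3962 and 11727 CPM, a log2 ratio of 1.57 (1.49 to 1.64). Cxcl3, a close paralog whose reads are hard to assign, had 0 and 438 UMIs and was at least 50.1-fold higher. Among osteoclastogenic signals, 10 of 12 measured genes were at least 2-fold higher (median 1.71). This list shares Il1b, Il1a, Tnf, Ptgs2, Osm, Ccl3 and Spp1 with the activation list. The recruiting chemokines share Cxcl2, Cxcl3, Ccl3 and Ccl4 with the activation list, so these medians are not separate evidence. The NF-kB list had a median of 0.91 and the dissociation and immediate early list 0.99.

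Secondary granule genes were lower, with a median of -0.66 over 11 genes (percentile 0), of which 2 were at least 2-fold lower. Chil3, a chitinase-like protein of maturing neutrophils, was at 3308 and 1565 CPM, 2.11-fold lower, but had a log2 ratio of -0.43 in cluster 5 alone. Camp, an antimicrobial granule peptide, had a log2 ratio of -0.45 (-0.49 to -0.41), but 0.20 in cluster 5 alone. Cxcr2, a chemokine receptor of mature neutrophils, was at 487 and 467 CPM, a log2 ratio of -0.06 (-0.30 to 0.19), but -0.67 (-1.08 to -0.25) in cluster 11 alone. The late maturation list had a median of 0.40, survival 0.73, and NADPH oxidase and NETs -0.20. Of the 10 named genes with the highest ratios, Cdkn1a, a cell cycle inhibitor, had 3 and 144 UMIs, a log2 ratio of 4.04 (2.47 to 6.34). The 10 lowest lay between -1.85 (Snw1) and -1.38 (Efcab14), on 17 to 36 OTM UMIs each.

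The class held 2 clusters in unequal parts. Cluster 11 was 36.4% of neutrophil-like cells in the control library (12 of 33) and 64.9% in the OTM library (96 of 148), and the rest was cluster 5, with the granule genes Ltf, Ngp and Lcn2 among its 10 leading genes. For list members with at least 3 UMIs expected in each library at equal CPM, the activation median was 0.29 in cluster 11 alone and 1.18 in cluster 5 alone, that of osteoclastogenic signals 0.45 and 0.84, and that of recruiting chemokines 0.51 and 1.61. For secondary granule genes it was 0.077 in cluster 11, over 5 of the 11 genes, and -0.11 in cluster 5. The late maturation median, 0.40 in the class, was -0.41 in cluster 11 and -0.20 in cluster 5. In the same order survival was at 0.23 and 0.47, the NF-kB list at 0.042 and 0.57, and the dissociation and immediate early list at 0.098 and 0.83. Il1b had log2 ratios of 0.23 and 1.96 in these clusters, and Tnf 0.92 and 0.40. Cxcl2 was at 21295 and 22816 CPM in cluster 11, and had a log2 ratio of 1.61 in cluster 5. In cluster 11 alone Il1a had a log2 ratio of 1.43 and Csf1 of 0.98, Cxcl3 had 0 and 437 UMIs and was at least 17.1-fold higher, and Cdkn1a had 0 and 115 UMIs and was at least 4.49-fold higher. Endothelial markers summed to 28.7 CPM in the control and 443 CPM in the OTM neutrophil-like cells, and osteoblast markers to 123 and 912 CPM. Spp1, one of these, had a log2 ratio of 5.07 (4.14 to 6.21) and was at 22360.5 CPM in the OTM osteoblast lineage-like cells. In cluster 11 alone Spp1 had 5 and 810 UMIs, a log2 ratio of 4.25 (3.02 to 5.87). The osteoblast markers Col1a1 and Bglap did not rise with it there. Col1a1 had a log2 ratio of -1.30 (-2.30 to -0.19), and Bglap had 3 and 6 UMIs. The source of the Spp1 UMIs was not tested.

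Macrophage or monocyte-like cells, the lineage that gives rise to osteoclasts, were compared to ask how precursors differed. Genes of antigen presentation and of resident macrophages were lower in the OTM library, and genes of lysosomes and glycolysis were higher, both by less in cluster m1 alone. H2-Aa, an MHC class II chain, was at 4185 and 1142 CPM, 3.67-fold lower, and Cd74, the class II chaperone, was 2.90-fold lower. Csf1r, the receptor of Csf1, was at 771 and 304 CPM, a log2 ratio of -1.34 (-1.60 to -1.08), but -0.11 in cluster m1 alone. Acp5, the osteoclast enzyme tartrate-resistant acid phosphatase, was at 25.1 and 581 CPM, a log2 ratio of 4.53 (3.40 to 5.98), and had 6 and 10 UMIs in cluster m1. The osteoclast markers, Acp5 among them, summed to 172 and 1033 CPM. In the OTM library Acp5 was also at 824 CPM in erythroid-like and 432 CPM in granulocyte progenitor-like cells, and at 19393 CPM in osteoclast-like cells. The gene Acp5 (ENSMUSG00000001348) lies on chromosome 9 at 22126727 to 22135711 on the minus strand.

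All 7 MHC class II genes were at least 2-fold lower, with a median of -1.54 (percentile 0.02). The class left out cluster m2 (12 control and 18 OTM cells), which scored highest for macrophages or monocytes. It stayed unnamed because its 10 leading genes held the dendritic cell markers H2-Eb1 and H2-Aa, both class II genes, and no macrophage or monocyte marker. The interferon genes Rsad2 and Ifit1 were also leading genes, so the MHC class II and interferon lists were compared without such cells. Of 13 measured resident macrophage genes, 7 were at least 2-fold lower (median -1.07, but 0.036 with doublets removed), among them Mrc1, the mannose receptor, which is a leading gene of cluster m1. Of 15 phagocytosis and lysosome genes, 7 were at least 2-fold higher and 1 lower (median 0.96, but 0.26 in cluster m1 alone and 0.20 as a mean over cells). Lgals3, a galectin, was at 792 and 4175 CPM and Ctsd, a lysosomal protease, at 402 and 1487 CPM. The hypoxia and glycolysis list had a median of 1.12 (0.22 in cluster m1 alone), osteoclast differentiation 0.52 and inflammatory monocyte 0.44. The cell cycle median was 1.84, but 0.26 with doublets removed, over the 5 of 14 genes with at least 3 UMIs expected in each library. In the dissociation and immediate early list 15 of 20 genes were at least 2-fold lower (median -1.37, but -0.43 in cluster m1 alone), among them the transcription factors Jun and Egr1 with log2 ratios of -2.24 and -2.25, but -0.58 and -0.36 in cluster m1 alone. Il1b had a log2 ratio of 0.81 (0.59 to 1.05), but -1.34 under the stricter filter, -1.33 with doublets removed and -1.35 with classes from each cell's own scores.

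The highest named ratio was that of Fabp5, a fatty acid binding protein with close paralogs, at 3 and 2907 UMIs, a log2 ratio of 7.67 (6.12 to 9.95). Lyz1, a lysozyme close to Lyz2, had 0 and 1859 UMIs and was at least 130.3-fold higher. Fabp5 is a leading gene of cluster m7 and Lyz1 of cluster m5. Among the 10 named genes with the lowest ratios, Nol4l had a log2 ratio of -5.88.

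Cluster m1 was 73.9% of the class in the control library (17 of 23 cells) and 19.4% in the OTM library (13 of 67), and clusters m7 and m8 held 9 and 10 OTM cells and 0 control cells. In cluster m1 alone the resident list had a median of 0.036 and MHC class II -1.28. For members with at least 3 UMIs expected in each library, the inflammatory monocyte list was at -0.83 there, with 1 of 8 genes higher, and osteoclast differentiation at 0.20. Spp1, a secreted phosphoprotein and leading gene of cluster m7 with a log2 ratio of 6.53 in the class, had -0.88 there, and Lgals3 0.11. Osteoblast markers, Spp1 among them, summed to 398 CPM in the control and 8253 CPM in the OTM cells of this class.

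Fibroblast-like cells, the collagen-producing cells of the ligament, were compared to ask how matrix and osteoclast-regulating genes differed. The class held 31 control and 417 OTM cells. It left out cluster 0 (91 control and 115 OTM cells), which also scored highest for fibroblasts and is compared below. The ratios therefore leave out most control cells that scored highest for fibroblasts. Mmp13, a collagenase, was at 453 and 4849.5 CPM, a log2 ratio of 3.42 (3.24 to 3.61), and Timp1, an inhibitor of such proteases, was 9.85-fold higher. Tnfsf11, which encodes the osteoclast differentiation factor RANKL, had 3 and 664 UMIs, a log2 ratio of 3.40 (1.85 to 5.68). Thbs4, a tendon matrix glycoprotein, was at 1637 and 238 CPM, 6.89-fold lower. Tnfsf11 (ENSMUSG00000022015) lies on chromosome 14 at 78277445 to 78308043 on the minus strand, and Mmp13 (ENSMUSG00000050578) on chromosome 9 at 7272514 to 7283331 on the plus strand.

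Of 14 cell cycle genes, 13 were at least 2-fold higher (median 2.85, percentile 100). Mki67, a proliferation marker, had 0 and 490 UMIs and was at least 7.79-fold higher. Of 13 osteoclastogenic signals, 7 were at least 2-fold higher and 2 lower (median 1.06). The 7 include the decoy receptor gene Tnfrsf11b, so they are not all osteoclast-promoting. Il11, a cytokine of the interleukin 6 family, had 3 and 764 UMIs, a log2 ratio of 3.60 (2.05 to 5.88). Ptgs2, the inducible prostaglandin synthase, had a log2 ratio of 1.96 and Tnfrsf11b, which encodes the RANKL decoy receptor, 2.78 (1.23 to 5.07). With classes from each cell's own scores these turned to -1.22 and -1.73. The recruiting chemokines had a median of 1.15, inflammatory monocyte genes 1.36 and the NF-kB list 0.76. Ccl2 is in each of these lists, and Csf1, Il6 or Ptgs2 is shared between each of them and the osteoclastogenic signals. The medians are therefore not separate evidence.

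The structural matrix differed less. Fibrillar and ligament matrix genes had a median of 0.08 over 23 genes, 5 of them at least 2-fold higher and 1 lower, and matrix remodelling genes 0.27 over 21. Col6a3, a collagen VI chain, had a log2 ratio of 1.44 (1.22 to 1.68). Tendon and ligament identity genes had a median of -0.29, with Tnmd, a tendon membrane protein, at a log2 ratio of -1.18 (-1.51 to -0.82) and Scx, a tendon transcription factor, at -0.54 (-1.05 to 0.02). The YAP and Wnt lists had medians of 0.00 and the TGF-beta and BMP list 0.09. The highest named ratio was that of Sfrp4, a secreted Wnt antagonist, with 6 and 8260 UMIs, a log2 ratio of 6.04 (4.91 to 7.48). The lowest was that of Col9a2, a collagen IX chain, at -3.92, which was -0.40 under the stricter filter.

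All 31 control cells of this class lay in cluster 9, which held 60.0% of the OTM cells. Clusters 18 and 19 held 28 and 139 OTM cells and 0 control cells, and Sfrp4, Mmp13 and Ccn5 are among their leading genes. In cluster 9 alone Mmp13 had a log2 ratio of 2.71, Tnfsf11 2.70 and Timp1 2.45, and the cell cycle median was 0.97. Neutrophil markers summed to 707 CPM in the control and 141 CPM in the OTM fibroblast-like cells.

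**Figure D2:**
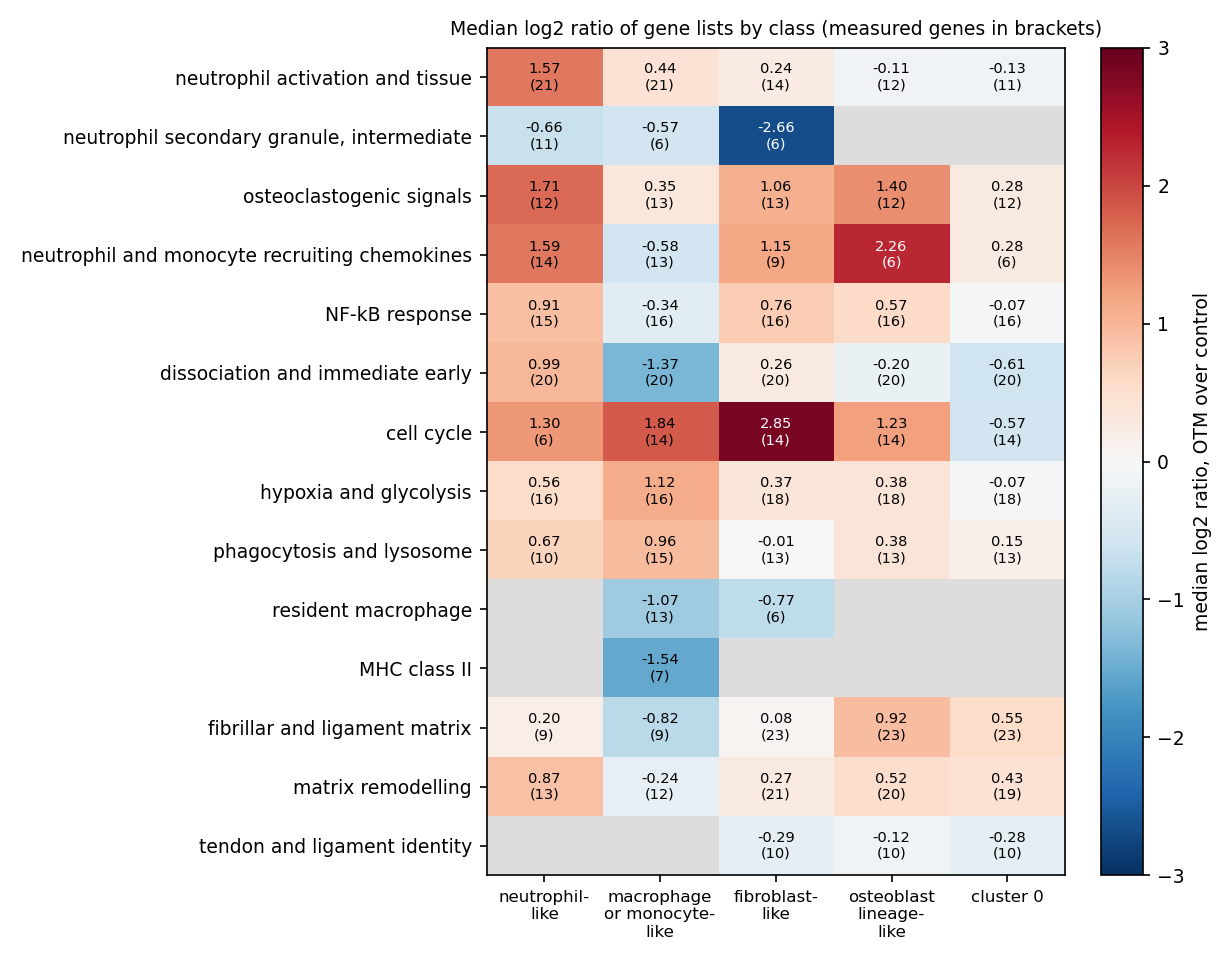
Median log2 ratio of OTM over control for 14 gene lists in 5 cell groups, as colour and number, with the count of measured genes in brackets. The activation list was at 1.57 in neutrophil-like cells, MHC class II at -1.54 in macrophage or monocyte-like cells and cell cycle at 2.85 in fibroblast-like cells.

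**Figure D3:**
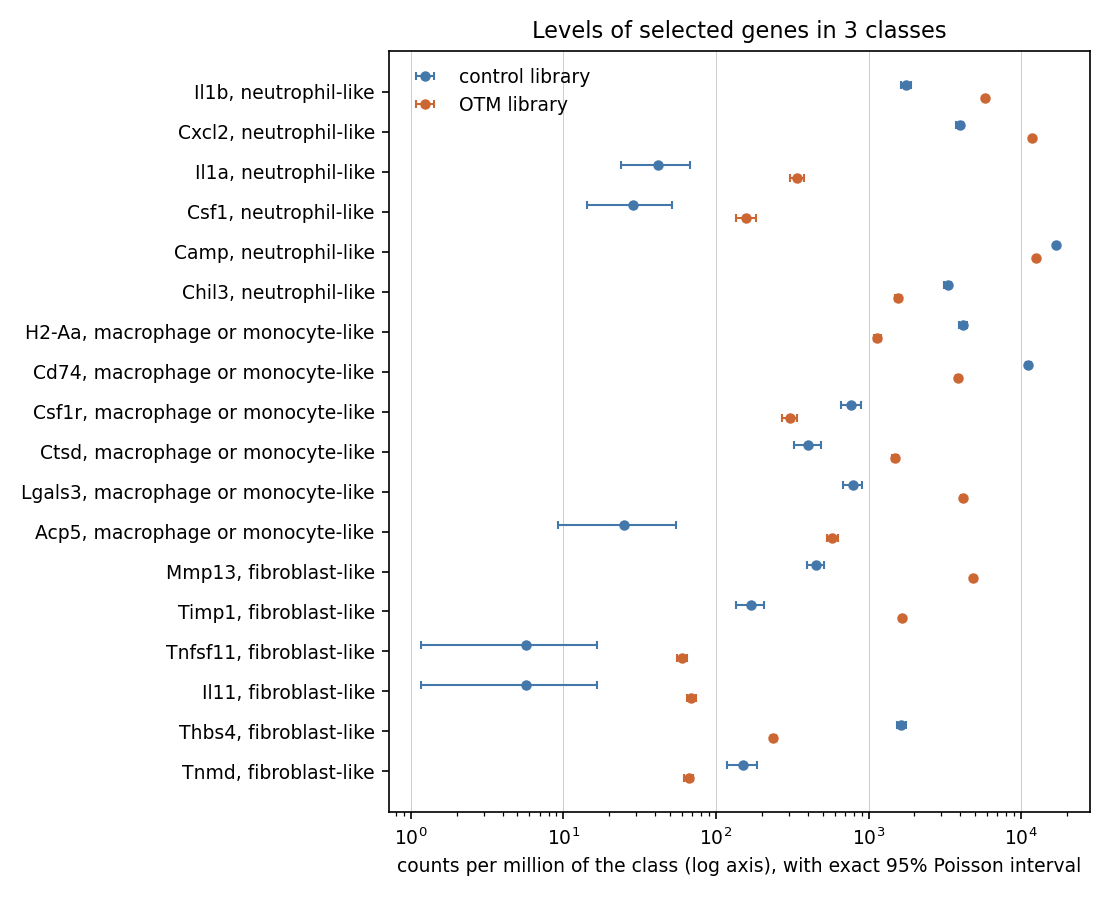
Levels of selected genes in CPM of the class on a log axis, with exact 95% Poisson intervals, in the control and OTM libraries. Il1b in neutrophil-like cells was at 1752 and 5813 CPM, and Thbs4 in fibroblast-like cells at 1637 and 238 CPM.

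Osteoblast lineage-like cells, which form bone, and cluster 0 were compared to ask whether other stromal cells differed in the same genes. In the osteoblast lineage, Tnfsf11 had 0 and 208 UMIs and was at least 16.9-fold higher, and Mmp13, a leading gene of cluster 13, had a log2 ratio of 6.11 (5.64 to 6.64), but 0.68 in cluster 8 alone. Postn, a matrix protein of the ligament, had log2 ratios of 3.10 (2.79 to 3.43) in the osteoblast lineage and 2.11 (2.02 to 2.20) in cluster 0. Bglap, which encodes osteocalcin, was at 7674 and 7776 CPM, but had a log2 ratio of 0.79 in cluster 8 alone. Cluster 13 was 34.4% of osteoblast lineage-like cells in the control library and 54.5% in the OTM library, and the rest was cluster 8. Fibrillar and ligament matrix genes had medians of 0.92 in the osteoblast lineage, or 0.14 in cluster 8 alone, and 0.55 in cluster 0. The osteoblast and cementoblast list had medians of 0.02 in the osteoblast lineage, or 0.59 in cluster 8 alone, and 0.45 in cluster 0. The cell cycle median, 2.85 in fibroblast-like cells, was 1.23 in the osteoblast lineage, or -0.28 in cluster 8 alone, and -0.57 in cluster 0. The NF-kB list was at 0.57 in the osteoblast lineage and -0.07 in cluster 0. In the same order recruiting chemokines were at 2.26 and 0.28, and osteoclastogenic signals at 1.40 (0.185 in cluster 8 alone) and 0.28. As stated above, these lists share members. In cluster 0, Tnfsf11 had 4 and 52 UMIs, a log2 ratio of 3.41 (1.97 to 5.34). Chil1, a chitinase-like protein, had the highest named ratio there, 5.12 (4.18 to 6.26), and Parvaos, an antisense transcript whose reads are hard to separate from its host gene, the lowest in the osteoblast lineage, -4.93.

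Levels of ligands and receptors were compared to ask which cells carried osteoclast-regulating signals. In the OTM library Tnfsf11 was at 60.0 CPM in fibroblast-like and 59.7 CPM in osteoblast lineage-like cells, which held 69.2% and 21.7% of its UMIs. Neutrophil-like cells had 0 UMIs of Tnfsf11, with upper bounds of 3.30 CPM in the OTM and 9.62 CPM in the control library. Its receptor Tnfrsf11a was at 224 CPM in osteoclast-like cells, a class added after it was seen, and at 85.5 CPM in macrophage or monocyte-like cells, against 58.7 CPM in the control. Neutrophil-like cells held 65.3% of the Il1b UMIs in the OTM library and 27.5% in the control library. These are shares of each library's own Il1b. In CPM of the whole library Il1b was not higher in the OTM library, so the shares do not show more Il1b in the loaded tissue.

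The whole libraries were compared because such sums need no clustering. Ccn5, a secreted matricellular protein, had 0 and 1913 UMIs and was at least 100.4-fold higher, and Sfrp4 and Tnfsf11 had log2 ratios of 4.40 (4.08 to 4.74) and 4.07 (3.14 to 5.20). Pcp4, a leading gene of cluster 0, had a log2 ratio of -3.44 (-3.55 to -3.33), or -1.30 once the control classes were weighted by the OTM shares. Under this weighting 7 of the 10 named genes moved out of their counting interval and 3 stayed within it. Primary granule genes of neutrophil precursors, such as Elane and Mpo, had a median of 3.83 over 7 genes. The share of granulocyte progenitor-like cells was 1.72% and 2.34%, and the markers of this class summed to 629 CPM in the control and 482 CPM in the OTM library, of which Chil3 made up 564 and 188 CPM. Osteoclast differentiation genes had a median of 0.57, with 8 of 26 at least 2-fold higher, and endothelial activation genes 0.99. Other lists were lower. Neutrophil activation genes, higher within neutrophil-like cells, had a median of -0.31 here, with 3 of 22 at least 2-fold higher and 3 lower. Late maturation genes were at -0.54, secondary granule genes at -1.33 and inflammatory monocyte genes at -0.27. Erythroid markers summed to 31373 CPM in the control and 7318 CPM in the OTM library, neutrophil markers to 38293 and 16063 CPM, osteoclast markers to 644 and 1979 CPM, and endothelial markers to 432 and 1180 CPM.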

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

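The shares without cluster 1, with cluster m2 or with cluster 0, and the values of single clusters, were alternatives chosen after seeing the data. No paired analysis was possible because each group was 1 pooled library. Over all settings, 853 gene values stayed within their counting interval, 404 moved and 22 reversed, where only a main log2 ratio of at least 1 or at most -1 with an interval off 0 could count as reversed, and other changes of sign, such as that of Il1b in macrophage or monocyte-like cells, count as moved; for list medians these numbers were 856, 107 and 9, and for shares 46, 8 and 2. The neutrophil-like share differed by -0.50 to 1.00 percentage points under every alternative, and the endothelial-like share by 9.32 to 10.4. The macrophage monocyte share differed by -5.89 to -1.86 points, with an interval that included 0 at the main settings, at both other resolutions and without cluster 1. Unless a reason is given, the cause was not tested.

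With doublets removed, no macrophage or monocyte-like cell was taken out, but the clusters were computed anew. The difference in the macrophage monocyte share was then -5.89 points, the resident macrophage median 0.036, and there Cxcl3 stood at -2.02 and Pf4 at 0.061. Under the stricter filter the differences in stromal and fibroblast-like shares were 10.9 and 12.8 points. The medians were -0.44 for secondary granule genes in neutrophil-like cells, -0.72 for resident macrophage and -1.33 for MHC class II genes, 0.28 for ligament matrix and -0.13 for cell cycle in the osteoblast lineage. Fcnb was at 0.53 in neutrophil-like cells.

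With classes from each cell's own scores, the stromal and fibroblast-like differences were 10.2 and 11.3 points. The medians were -0.63 for resident macrophage, -2.30 for MHC class II, 0.63 for matrix remodelling in fibroblast-like cells and -0.75 for cell cycle in neutrophil-like cells. Among fibroblast-like cells Igfbp3 was at -1.38, Cap2 at 1.22, Ptgs2 at -1.22, Tnfrsf11b at -1.73 and Tnc at -0.36. With cells thinned to 1500 UMIs, the stromal share differed by -13.3 points and the fibroblast share by -8.71 points. With each library clustered alone they were 1.12 and 38.6 points, because the control library then had no fibroblast-like cluster. With cluster 0 counted as stromal, the difference was 3.53 points.

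As a mean over cells, the medians were 0.93 for activation, -0.91 for secondary granule and 1.25 for osteoclastogenic genes in neutrophil-like cells, and -1.03 for MHC class II and 0.20 for phagocytosis in macrophage or monocyte-like cells. Centred on the median gene, secondary granule was at -0.86 and MHC class II at -1.46.

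In the cluster of each class with most control cells alone (5, m1, 9 and 8), cells of other clusters no longer counted. Neutrophil-like medians were 0.98 for activation, -0.11 for secondary granule and 0.52 for osteoclastogenic signals, and Ccl3 was at -0.036. Macrophage medians were 0.036 for resident, -1.28 for MHC class II and 0.26 for phagocytosis genes. Phactr2 was at 0.90, Pf4 at 0.036, F13a1 at 0.11, Adgre1 at 0.022, Ctsl at -0.22, Spp1 at -0.88 and Aldoa at -0.10. The fibroblast-like cell cycle median was 0.97. In the osteoblast lineage, ligament matrix was at 0.14 and cell cycle at -0.28. In cluster 11 alone, activation was at 0.23, osteoclastogenic signals at 0.43 and Icam1 at -0.41 (40 and 257 UMIs).

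The floor of 3 UMIs lies higher in CPM in the library with fewer UMIs, so that a sum too small for it gets a sign from the floor. The following values therefore show no direction. In cluster 5, Maml3 (0 and 3 UMIs) and Rtp4 (1 and 3) stood at -0.89. Hist1h2ap in cluster 9 (1 and 29 UMIs) stood at -0.13, against 1.45 (-1.14 to 6.80) by its counts. Ccdc162 in the osteoblast lineage stood at -1.17 under the stricter filter (1 and 4 UMIs) and at -1.28 in cluster 8 (0 and 3). In cluster 11, secondary granule genes stood at -0.93, cell cycle at -1.29 and endothelial activation at -0.59. In macrophage or monocyte-like cells, cell cycle stood at -0.61 with doublets removed and tendon genes at 0.16 in cluster m1. For members with at least 3 UMIs expected in each library at equal CPM, a choice made after seeing the data, secondary granule was at 0.077 in cluster 11 (5 of 11 genes), endothelial activation at -0.32 (3 of 9) and cell cycle with doublets removed at 0.26 (5 of 14). Only 2 cell cycle and 2 tendon genes were left in the other cases. All 120 list medians of whole classes that kept at least 3 such members stayed within their counting interval.

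Of the 20 named genes per class, 10 in neutrophil-like, 15 in macrophage or monocyte-like and 11 in fibroblast-like cells were named again with a minimum of 50 UMIs. Depth limits the control classes most, with 33, 23 and 31 cells in these 3 classes.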

Other observations

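All tests of explanations in this part were chosen after the result was seen. Endothelial-like cells, a class added after it was seen, carried transcripts of Csf3, Ccl2 and Cxcl1. In the OTM library, Csf3, the granulocyte growth factor, was at 309 CPM in these cells, against 81.0 CPM in the 14 control cells, and Ccl2, a monocyte attractant, at 1023 and 405 CPM. Cxcl1 was at 1102 and 923 CPM. Epithelial-like cells carried Cxcl5, another attractant, at 411 CPM in the control library and 1930 CPM in the OTM library. Mural-like OTM cells held 40.5% of the library's Il6. Osteoclast-like cells held 85.7% of the OTM library's Acp5 and 56.4% of its Ctsk, the collagen-degrading cathepsin K.

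The interferon list was at 0.79 in neutrophil-like, -0.37 in macrophage or monocyte-like and 0.01 in fibroblast-like cells, or 0.96, -0.25 and 0.54 for members with at least 3 UMIs expected in each library. ER stress was at 0.39, -0.02 and 0.40 in the same order. The dissociation and immediate early list differed in direction between classes, with 0.99 in neutrophil-like (0.098 in cluster 11 alone for members with at least 3 UMIs expected in each library), -1.37 in macrophage or monocyte-like (-0.43 in cluster m1 alone), 0.26 in fibroblast-like, -0.20 in osteoblast lineage-like cells and -0.61 in cluster 0. Whether these differ beyond variation between mice was not tested.

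Activation genes were higher in the neutrophil-like cells of the OTM library, with a median of 1.571. Endothelial RNA or doublets are argued against, because the median was 1.587 without the 2 control and 7 OTM barcodes of 2 or more endothelial marker UMIs. A stronger handling response of the whole OTM library is argued against by the dissociation list median of -0.608 in cluster 0. That value cannot speak to a handling response of neutrophil-like cells alone. Their dissociation list median was 0.99, so this stays open. A larger part of cluster 11 may account for part of the pattern, as with the control clusters weighted by the OTM shares of UMIs the median was 0.33. That value met the bound set for this explanation. Activation genes help to define cluster 11, however. In cluster 5 alone the activation median was still 0.98 and the log2 ratio of Il1b 1.96. How much the larger part of cluster 11 accounts for thus stays open. Whether loading brought in or activated such cells stays open, since 1 library per group cannot show it.

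The 10 named genes with the highest ratios in fibroblast-like cells had a median log2 ratio of 3.952. Free RNA from other cells is argued against for these genes only, because their median level in OTM neutrophil-like cells was 3.446% of that in fibroblast-like cells. The naming rule had already left out markers of other classes and genes below 10% of their highest class. A low value was therefore likely from the start. Clusters 18 and 19, which held OTM cells alone, could account for part of it, since the median was 2.702 in cluster 9 alone. That value lies between the bounds set for the test, and an effect of loading remains an untested hypothesis.

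Resident macrophage and MHC class II genes were both lower in the OTM macrophage or monocyte-like cells. For the resident genes, fewer cells of cluster m1 may be the reason, as their median was 0.036 in cluster m1 alone. Mrc1, Pf4 and Cd163 of this list help to define that cluster, however, so how much this shift accounts for stays open. For the MHC class II genes the same shift is argued against as the whole cause, because their median was -1.278 there, on 17 control and 13 OTM cells. A lower class II level with loading is therefore a hypothesis to follow up, for a class that left out cluster m2. The 3 tests planned for a difference in the neutrophil-like share were not run, because that difference lay within counting error.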
